A study of Mus musculus with 4 samples.

How the data were processed

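The data are peak lists from ChIP-seq of HA-tagged Fbxl10 in mouse embryonic fibroblasts, with and without doxycycline (1 µg/ml, 48 hours). Per the labels' protocols, 7 µg of chromatin was precipitated with 5 µg of HA antibody after enzymatic fragmentation, and libraries were sequenced on an Illumina instrument. The submitters' processing notes name Bowtie2 and the mm10 build, with no version. The names of the peaks show that the authors called them with MACS, per the peak names in the files. The version, the threshold and the pooling of samples are not given in the sources used here. The names of both lists hold the mark inp, which may stand for input. How the input libraries were used is not stated. Each deposited list gives the position of each peak and a score, which the authors' caller wrote and whose formula is not given in the sources used here. Scores were used to rank peaks within a list and to count and class the peaks of both lists at the same score limits. In 1 alternative they were used to filter both lists at the same score. The lists carry no read counts, so depth is unknown. The input libraries were not used here.

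Groups came from the titles of the 4 libraries, whose marks for with and without were read as with and without doxycycline because the libraries marked as with also carry the induction label. The 2 lists were assigned by the same marks. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Kdm2b, the 8 highest-scoring border peaks of each class (induced-only, shared and non-induced-only), the 3 highest peaks of each list, and, per gene list, up to 4 members with the highest induced and 2 with the highest non-induced peak. Some genes that the rule takes are not reported here.

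Genes were taken from a RefSeq gene table of assembly GRCm38.p6, which has the coordinates of mm10. It gives the start and end of each gene without strand or exons, and no genome sequence was used. The planned test at transcription start sites therefore became a test at gene borders, meaning either end of a protein-coding gene, within 1 kb. The planned measurements of CpG content, CpG-rich promoters, repeats and Kdm2b exons were not run, and the whole Kdm2b gene was used for the last. In the list of housekeeping genes Malat1 and Neat1 were not matched, since they are not protein-coding.

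Peaks were shared when they overlapped by at least 1 bp. Random expectation came from 1000 placements of each peak on its own chromosome between the first and the last gene; gaps and unmappable sequence were not excluded. The places of random peaks within and between genes used 100 placements. Shares have exact Clopper-Pearson intervals at 95%, and a share of 0 has an upper limit of 3 counts of its total. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment at 0.05. Where a cell of the table was 0, 0.5 was added to each cell for the odds ratio, which is then a fitted value. Neighbouring genes can share a peak, so genes are not independent and these p-values are too small for clustered genes. Scores of shared and other peaks were compared by permutation tests with 100000 permutations, as were the correlations across chromosomes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

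On the lists themselves, the number of the 5497 induced peaks that the overlap function found shared differed from that of bedtools 2.31.1 by 0. In tests on simulated data, a border share of 33.2% was recovered as 33.4% over 5493 peaks. Of simulated lists of 50 genes among 21887, 97% with an odds ratio of 4 and 3.6% with an odds ratio of 1 had p under 0.05. Simulated genes were marked independently of each other, so these rates do not cover clustered genes that share peaks. Alternatives were a score at or above the joint median of both lists (61.6), lists of equal size, an overlap of 50% of the shorter peak, a gap of 1 kb, border windows of 500 bp and 5 kb, and no mitochondrial or Y chromosome. Added after the data were seen were the removal of 1 Mb bins with at least 3 shared peaks, a background without olfactory and vomeronasal receptor genes and sex chromosomes, and 1 gene per 100 kb. The joint median treats the scores of both lists as on a common scale, which was not tested. Overlaps under alternatives were set against 200 placements.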

Results

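The series asked where Fbxl10, the histone demethylase also called Kdm2b, sits on chromatin when it is overproduced. Mouse embryonic fibroblasts (MEFs) carried an HA-tagged Fbxl10 that doxycycline switches on, here at 1 µg/ml for 48 hours. Chromatin immunoprecipitation with an HA antibody and sequencing (ChIP-seq) was done on induced and non-induced cells, with an input library for each. The labels describe 4 libraries, 1 in each of 4 groups, and 1 peak list for each of the 2 ChIP groups was analysed here. The protocol speaks of 3 independent samples, and how these relate to the 2 lists is not given in the sources used here. With 1 list per condition there was no replicate check, so every test compares the lists and not the conditions. Read totals are unknown, and intervals are exact 95% binomial intervals that cover counting error only.

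The induced list held 5497 peaks and the non-induced list 10532, which is 1.92 times as many. Induced peaks were wider, with a median of 758 bp against 586 bp, and covered 4816 kb against 6528 kb. Peak scores, the authors' own value for each peak, began at 50 in both lists. In the induced list 1165 peaks (21.2%) had a score of at least 100, and in the non-induced list 378 peaks (3.59%). This sets both lists at the same score, and a common scale was not tested. Kdm2b itself, on chromosome 5 from 122870664 to 122989270 (mm10, gene 30841), had 0 peaks in either list. The nearest induced peak was 68.5 kb away and the nearest non-induced peak 693 kb.

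Few sites were found in both lists. Of the induced peaks, 185 (3.37%, interval 2.90 to 3.88) overlapped a non-induced peak, and of the non-induced peaks 187 (1.78%, 1.53 to 2.05) overlapped an induced one. Shared peaks at borders of genes included those of Osr2, a transcription factor of limb and palate development (score 298 induced and 69.9 non-induced), the collagen IV pair Col4a1 and Col4a2 (231 and 56.6), and Nrp2, a semaphorin receptor (211 and 59.4). Abhd11 (224 and 65.8), Gm7592 (251 and 85.0) and Gm42346 (677 and 362) also had shared border peaks. Whether scores from different lists are on a common scale was not tested. The overlap was 5.39 times that of 1000 random placements of the induced peaks (mean 34.3, SD 5.93, maximum 53; one-sided permutation p = 0.001, the smallest they can give). Shared peaks had higher scores than the others of their list, by a median of 27.4 in the induced list (93.5 against 66.2) and 10.8 in the non-induced list (70.9 against 60.1). Both two-sided permutation p-values were 1e-05, the smallest that 100000 permutations can give. Shared peaks were also wider, with medians of 1053 bp against 752 bp (induced) and 792 bp against 586 bp (non-induced). The tests of score did not account for width. Without the 9 bins of 1 Mb that held 3 or more shared peaks, a choice made after the data were seen, the overlap fell to 1.86%. The score difference fell to 21.7 in the induced and 4.65 in the non-induced list (two-sided permutation p = 1e-05 and 0.0008).

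Induced peaks were frequent at the ends of protein-coding genes, and non-induced peaks were rare there. A border is here either end of a gene, since the annotation used gave no strand, and a peak within 1 kb of it was counted. Of 5308 induced-only peaks 2543 (47.9%, 46.6 to 49.3) were at a border, and of 10345 non-induced-only peaks 292 (2.82%, 2.51 to 3.16). The odds ratio was 31.7 (27.9 to 36.0), with a two-sided Fisher's exact p below the smallest number double precision can hold. Random placements gave 4.38% (SD 0.274) for the induced and 3.78% (SD 0.190) for the non-induced list. These placements were of the whole non-induced list, of which 332 of 10532 peaks (3.15%) were at a border. That was within the range of the 1000 placements (3.12% to 4.34%) but under their mean (one-sided permutation p = 0.002). The non-induced-only share lay below the lowest placement (one-sided permutation p = 0.001, the smallest possible), but the placements did not leave out shared peaks. Peaks shared by both lists were at borders in 25.9% (19.8 to 32.9) of cases by the induced list. With a window of 5 kb the odds ratio was 15.9, with 63.4% of induced-only and 9.81% of non-induced-only peaks at a border.

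The induced-only border peaks with the highest scores lay at Gm3417 and 9030025P20Rik (419.55, chromosome 17, 14977523 to 14979472), and at Tchh, which encodes the hair follicle protein trichohyalin (404). Ndufaf3, a complex I assembly factor, shared a peak with Dalrd3 and Impdh2 (398, chromosome 9, 108566165 to 108568441). Next came the receptor phosphatase Ptprg (383), the intermediate filament gene Nes (342), Sdf2l1 (336), Lbh (334) and B3gnt2 (325). Among non-induced-only border peaks the highest were at Gm52481 on chromosome Y (319.99), Zfp992 (156), the ubiquitin-conjugating enzyme gene Ube2d3 (154), the germ cell helicase gene Ddx4 (146), Mucl2 (142), Prdm10 (138), Urm1 (136) and Eea1 (127).

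Border peaks were more frequent among induced peaks of higher score. The share was 30.6% (28.1 to 33.3) for scores of 50 to 55 and 69.1% (65.0 to 72.9) for 120 to 200. It was 63.8% (55.5 to 71.5) from 200 upward, and outside the bins with 3 or more shared peaks 74.4% (65.8 to 81.8). In the non-induced list it was 2.77% (2.22 to 3.41) and 10.2% (5.37 to 17.1) in the first and the sixth of these classes, and 8.11% (1.70 to 21.9) of 37 peaks from 200 upward. Outside those bins 0 of 8 non-induced peaks from 200 upward were at a border (interval 0 to 36.9%). Midpoints of induced-only peaks within 1 kb of a border lay a median of 165 bp inside the gene, on a scale where the inside is negative (-165 bp), and 63.6% of them were inside. Between genes lay 17.9% of induced peaks, against 47.7% of random placements, and 53.7% of non-induced peaks, against 48.8%.

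**Figure D1:**
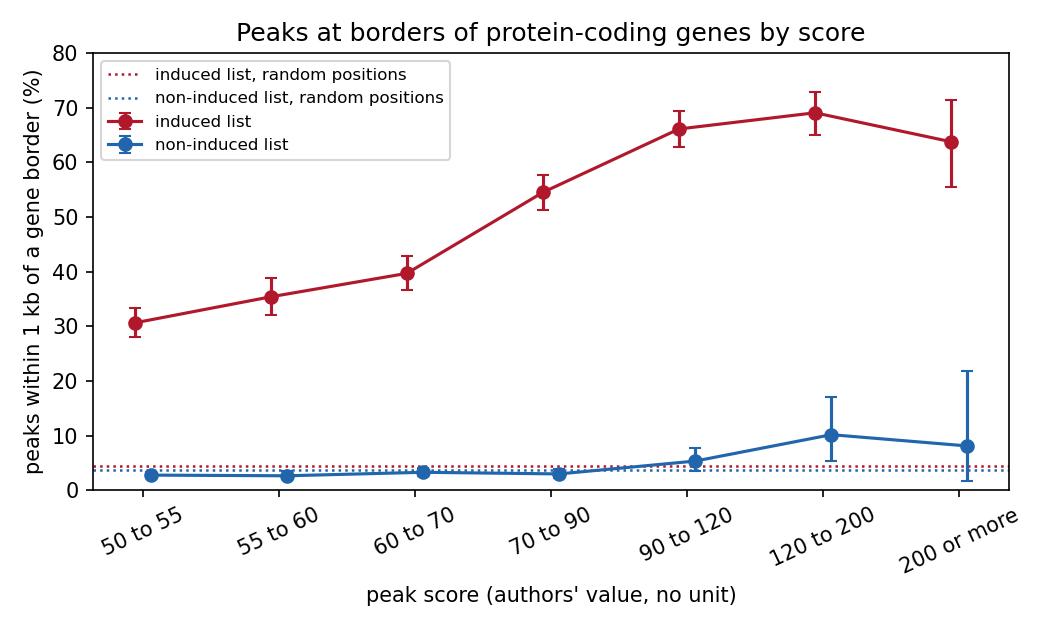
Percent of peaks within 1 kb of a border of a protein-coding gene (vertical axis) by class of peak score (horizontal axis, authors' value without a unit), for the induced and the non-induced list, with exact 95% binomial intervals and the mean of random placements as dotted lines. The induced share goes from 30.6% in the lowest class to 69.1% for scores of 120 to 200, and the non-induced share stays at or below 10.2%.

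**Figure D2:**
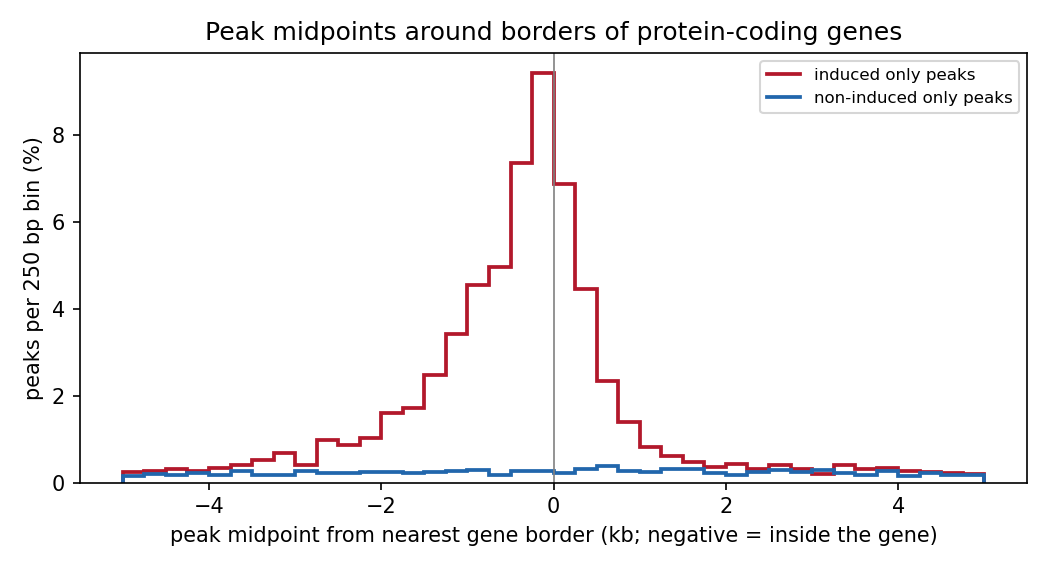
Distance in kb from the peak midpoint to the nearest border of a protein-coding gene (horizontal axis, negative inside the gene), as percent of induced-only and non-induced-only peaks per bin (vertical axis). Induced-only midpoints gather at the border and slightly inside it, and non-induced-only midpoints show no such rise.

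Of 21887 protein-coding genes, 2930 (13.4%, 12.9 to 13.8) had an induced peak at a border and 348 (1.59%, 1.43 to 1.76) a non-induced peak. Both lists marked 74 genes, where independent lists would share 46.6 (odds ratio 1.77, 1.36 to 2.29, two-sided Fisher's exact p = 4.56e-05). The 19 gene lists fixed before the data were examined were each tested in both peak lists with two-sided Fisher's exact tests, and the 38 p-values were adjusted by Benjamini and Hochberg. In the induced list 9 gene lists lay above the other genes, 1 below, and 9 did not pass. In the non-induced list 3 lay above and 16 did not pass.

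Histone genes were marked most often. Of 65 replication-dependent histone genes 41 (63.1%, 50.2 to 74.7) had an induced peak, an odds ratio of 11.2 (adjusted exact p = 3.36e-19), and 0 had a non-induced peak, which allows up to 4.62%. H2ac19 and H3c15 shared a peak (score 173), as did H2ac22 and H2bc22 (162). The histone genes lie in clusters, and 31 different peaks stood behind the 41 genes. With 1 gene per 100 kb, a choice made after the data were seen, 3 of 6 remaining histone genes had a peak and the list no longer passed (odds ratio 6.85, adjusted exact p = 0.146).

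Developmental regulators were also marked. Of 80 developmental transcription factor genes 29 (36.3%) had an induced peak (odds ratio 3.71, adjusted exact p = 2.59e-06), among them Hand2 of heart and limb (182), the Wilms tumour gene Wt1 (155) and the limb and mammary factor Tbx3 (153). In the non-induced list 1 had a peak, Zic2 (80.2). Of 49 genes of Wnt, Notch, TGF-beta and hedgehog signalling 18 (36.7%) had an induced peak (odds ratio 3.77, adjusted exact p = 0.000252), among them the Notch ligand Jag1 (194), the Wnt receptor Fzd2 (157), Lef1 (133) and Wnt11 (133). Of the same list 5 (10.2%) had a non-induced peak (odds ratio 7.12, adjusted exact p = 0.00504), with Wnt3 (91.7) and Lef1 (78.9) highest.

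Hox genes, which pattern the body axis, were marked in both lists. In the induced list 10 of 39 (25.6%) had a border peak, among them Hoxa7 (279.53), Hoxd11 (151), Hoxc5 (121) and Hoxb9 (92.0), and the list did not pass (odds ratio 2.24, adjusted exact p = 0.0836). In the non-induced list 6 (15.4%) did, Hoxb8 (89.0) and Hoxa13 (70.9) highest, and the list passed (odds ratio 11.4, adjusted exact p = 0.000252). Within 5 kb, 28 of the 39 had an induced peak and the list passed there too (odds ratio 11.4, adjusted exact p = 4.38e-12). Neighbouring Hox genes can share a peak, and the different peaks behind these 28 genes were not counted. At 1 kb, keeping 1 gene per 100 kb left 7 Hox genes. Of these 3 had an induced peak, and the list did not pass (odds ratio 5.14, adjusted exact p = 0.185). In the non-induced list 1 of the 7 had a peak, the odds ratio was 9.37 and the call was lost (adjusted exact p = 0.341). Among peaks at or above the joint median score the non-induced odds ratio was 6.40 and the call was lost too (adjusted exact p = 0.163).

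Immediate early genes, cell cycle genes and cell cycle inhibitors passed in the induced list. Of 25 immediate early genes, which respond first to growth factors, 11 (44.0%) had a peak (odds ratio 5.10, adjusted exact p = 0.00112), with Atf3 (189), Jun (161), Egr3 (130.43) and Jund (129.52) highest. Of 58 cell cycle and DNA replication genes 16 (27.6%) did (odds ratio 2.47, adjusted exact p = 0.0127), with Ccnd1 (249.65), Myc (157), Rb1 (150.5) and Bub1 (141) highest. Of 15 cell cycle inhibitor and p53 genes 6 (40.0%) did (odds ratio 4.32, adjusted exact p = 0.0284), with Trp53 (181), Cdkn2b (139), Cdkn2a (109.85) and Sesn2 (99.8) highest. None of the genes in these lists had a non-induced peak, which allows up to 12%, 5.17% and 20% of them. The cell cycle list lost its call without receptor genes and sex chromosomes (odds ratio 2.18, adjusted exact p = 0.0520) and with 1 gene per 100 kb (1.24, adjusted exact p = 1). The inhibitor list lost its call in these settings and among the higher scores, with odds ratios of 3.71, 5.14 and 4.61 (adjusted exact p = 0.0593, 0.185 and 0.0555).

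Ribosomal protein, glycolysis and housekeeping genes were marked above the others too. Of 83 cytosolic ribosomal protein genes 23 (27.7%) had an induced peak (odds ratio 2.49, adjusted exact p = 0.00277), with Rpl41 (239), Rpl37a (201), Rps18 (156) and Rps27l (155) highest. Of 19 glycolysis genes 7 (36.8%) had one (odds ratio 3.78, adjusted exact p = 0.0280), with Gpi1 (211), Pfkl (151), Gapdh (137) and Pkm (118) highest. Of 25 abundant housekeeping genes 9 (36.0%) did (odds ratio 3.65, adjusted exact p = 0.0127), among them Ncl (110.16), Tuba1a (83.7) and B2m (82.6). Among peaks at or above the joint median score these calls were lost, with odds ratios of 1.87, 2.46 and 1.75 (adjusted exact p = 0.163, 0.295 and 0.636), and likewise with 1 gene per 100 kb, with odds ratios of 1.93, 6.85 and 1.71 (0.330, 0.0764 and 0.829). Glycolysis also lost its call without receptor genes and sex chromosomes, at an odds ratio of 3.54 (adjusted exact p = 0.0515).

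Olfactory receptor genes, which encode the odour receptors of the nose, had no induced peak: 0 of 1106, which allows up to 0.271% (adjusted exact p = 6.79e-70). In the non-induced list 31 (2.80%) had one (odds ratio 1.86, adjusted exact p = 0.0115), with Olfr1436 (102) and Olfr437 (87.1) highest. That call was lost at higher scores, with 1 gene per 100 kb, within 5 kb and with lists of equal size, at odds ratios of 1.19, 1.74, 1.30 and 1.2 (adjusted exact p = 0.916, 0.341, 0.0853 and 1).

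Other lists did not pass in either peak list. Of 39 fibroblast and extracellular matrix genes 10 had an induced peak (odds ratio 2.24, adjusted exact p = 0.0836), among them Ccn1 (211), Thbs1 (207), Tpm1 (185) and Thy1 (115). Of 98 oxidative phosphorylation genes 17 did (odds ratio 1.36, adjusted exact p = 0.560), led by Ndufaf3 (398), Ndufs7 (147) and Cox6a1 (146), and 2 had a non-induced peak, Ndufaf4 (64.8) and Atp5l (54.9). Cholesterol and fatty acid synthesis had 5 of 26 (Fdps 116, Srebf2 111) and pluripotency 4 of 20 (Klf5 115, Sox2 114). Of 10 genes of PRC1.1, the Polycomb complex that contains Kdm2b, 2 did, Pcgf1 (177) and Rybp (86.4). Without receptor genes and sex chromosomes 8 of the 10 were left, with the same 2 marked (odds ratio 1.85, adjusted exact p = 0.902). Markers of other cell types had 2 of 20 each: Grin1 (77.9) and Slc17a7 (50.04) of neurons, Klf1 (122) and Cd14 (110.42) of blood, and Kdr (92.4) and Cdh1 (52.5) of endothelium and epithelium.

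**Figure D3:**
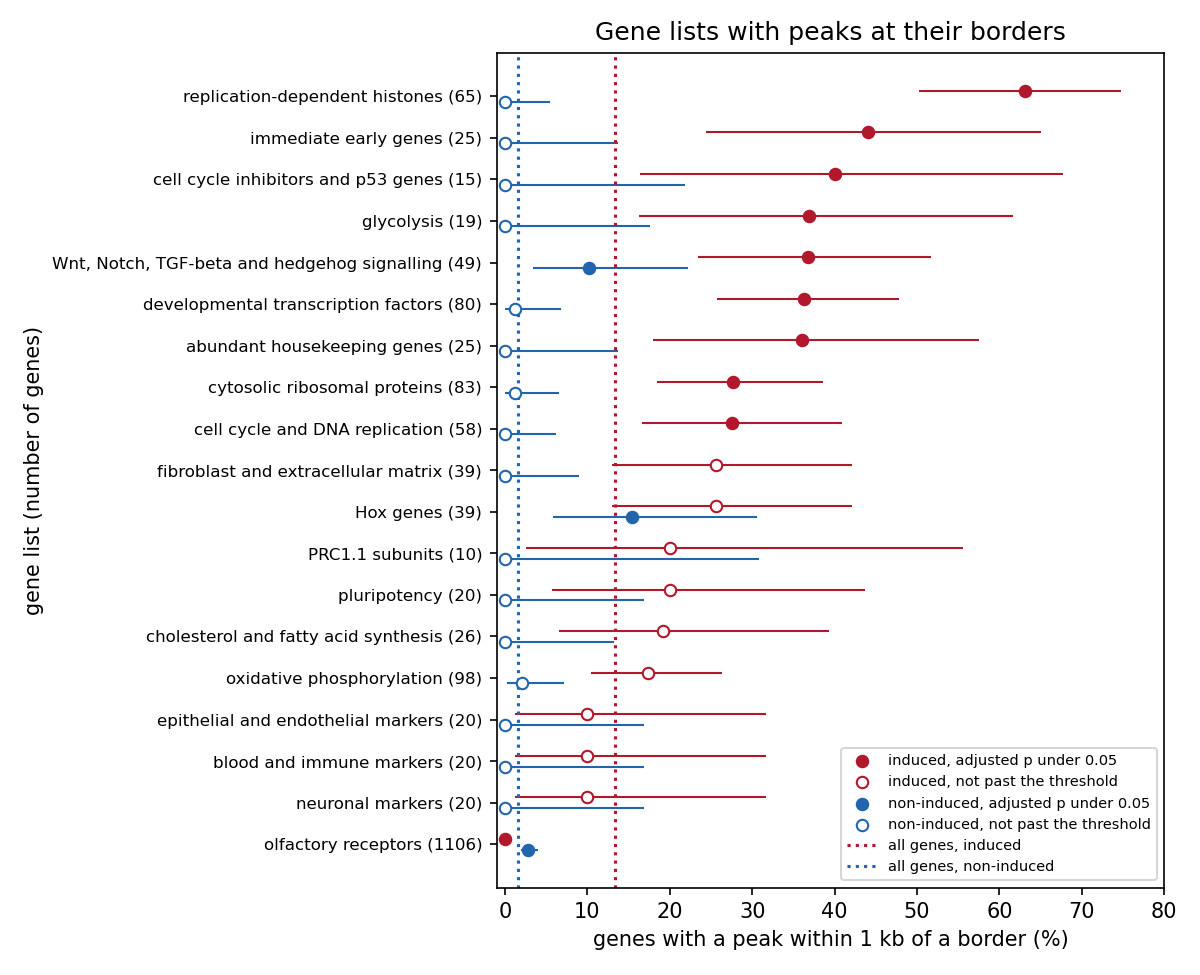
Percent of the genes of each list with a peak within 1 kb of a border (horizontal axis) for the 19 gene lists (vertical axis, number of genes in brackets), in the induced and the non-induced list, with exact 95% binomial intervals. Filled points have an adjusted p under 0.05 and dotted lines give the share of all genes, 13.4% induced and 1.59% non-induced; histone genes reach 63.1%.

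A direct comparison used the 2856 genes marked in the induced list alone and the 274 marked in the non-induced list alone. Olfactory receptors were split 0 to 31 (adjusted exact p = 6.11e-33 over 19 lists). Hox genes were split 10 to 6, which is a larger non-induced part than in other genes (odds ratio 0.157, 0.0566 to 0.435, adjusted exact p = 0.0152). The Hox result was lost with higher scores (odds ratio 0.256, adjusted exact p = 0.777) and with lists of equal size (0.175, adjusted exact p = 0.238), and within 5 kb its odds ratio turned to 1.8 (adjusted exact p = 0.715). Histone genes were split 41 to 0, the most extreme split possible for 41 genes, and still did not pass (adjusted exact p = 0.291). With 274 genes in the non-induced list alone, the test at 1 kb could not call a larger induced part for lists with this many marked genes or fewer. Within 5 kb histone genes were split 50 to 1 and passed (odds ratio 11.9, adjusted exact p = 0.00436). Neighbouring histone genes can share a peak, and the different peaks behind these genes were not counted at 5 kb. That p-value is therefore too small. Developmental transcription factors were split 29 to 1 (adjusted exact p = 1), and within 5 kb 42 to 1, where they passed (odds ratio 9.93, adjusted exact p = 0.0164).

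Chromosomes rich in genes had more induced peaks. Across the 19 autosomes, induced peaks per Mb went with protein-coding genes per Mb (Pearson's r = 0.688, permutation p = 0.00116, adjusted 0.00203; Spearman's rho = 0.796, permutation p = 6e-05, adjusted 0.00012). Without chromosomes 11 and 7, farthest from the median in gene density, r was 0.811. Non-induced peaks went the opposite way (r = -0.659, permutation p = 0.00203, adjusted 0.00203; rho = -0.511, permutation p = 0.0273, adjusted 0.0273), but the call rests on these chromosomes: without them r was -0.443 (permutation p = 0.0747) and rho -0.316 (permutation p = 0.215), still negative. Chromosome X had 14 induced peaks (exact Poisson interval 7.65 to 23.5) where the autosomal rate predicts 382, and 47 non-induced peaks (34.5 to 62.5) where it predicts 731. Of these, 8 induced and 6 non-induced peaks lay in the last 2 Mb of the annotated chromosome, and the 6 induced peaks elsewhere had scores of at most 73.1 and the 41 non-induced ones of at most 202. None of its 966 genes had an induced peak, which allows up to 0.311%, against 14.2% of autosomal genes (two-sided Fisher's exact p = 3.83e-63).

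**Figure D4:**
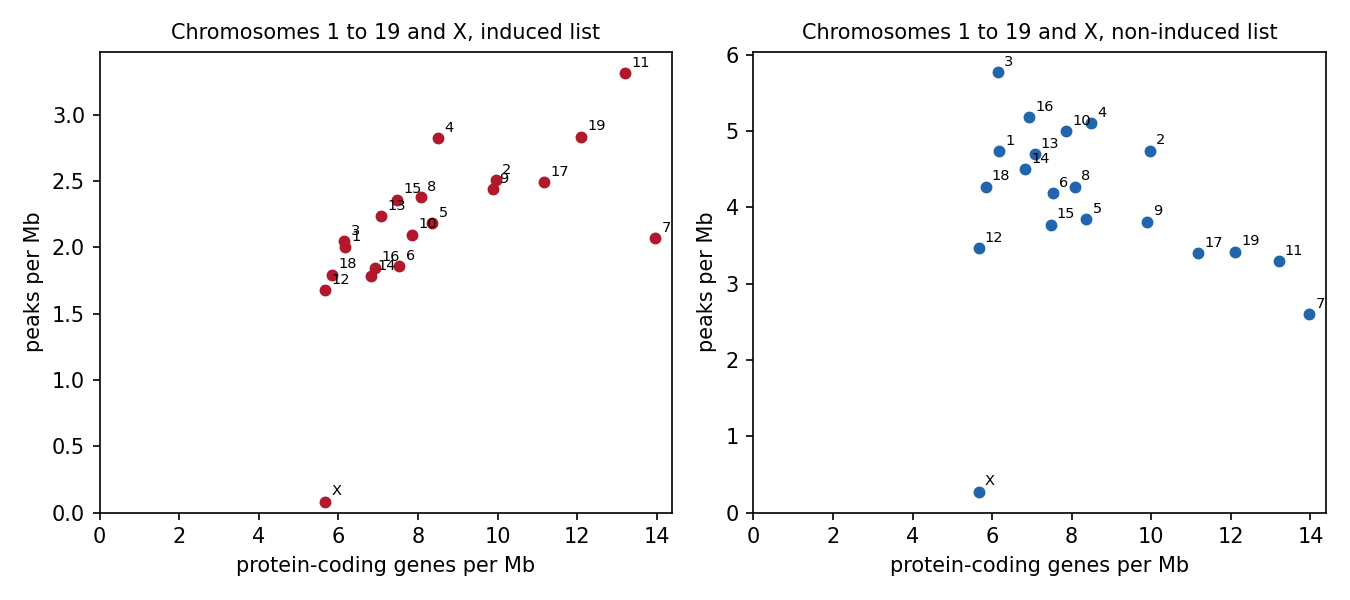
Peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis) for chromosomes 1 to 19 and X, in the induced list (left) and the non-induced list (right), each point a chromosome. Chromosome X lies near the bottom in both, at 0.0820 and 0.275 peaks per Mb.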

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

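All tests in this part except that of the reading of the list names were chosen after the results were seen. A signal outside the main comparison was seen on the mitochondrial genome: the induced list had 4 peaks there, and the non-induced list 0. The highest, with a score of 723, covered the mitochondrial ribosomal RNA genes (positions 3 to 2847).

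The non-induced list was the longer, although HA-Fbxl10 had not been switched on. If the lists were 1 ChIP called with and without an input control, at least 95% of the shorter list should lie in the longer, and 3.37% did, which argues against that reading. HA-Fbxl10 made without doxycycline would place many non-induced peaks on induced ones, and 1.78% overlapped, which argues against it as the source of the count. Background calls placed at random would give the border share of random placements. The whole non-induced list had 3.15%, within the range of these (3.12% to 4.34%) but under their mean of 3.78% (one-sided permutation p = 0.002). The non-induced-only share of 2.82% lay below that range, but the placements did not leave out shared peaks. This comparison therefore does not settle random placement. Background calls placed in another way, sequencing depth and the control used for each list were not tested and stay open.

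Chromosome X was nearly empty in both lists. Chromosome Y, with 2.82 genes per Mb, also had few peaks: 19 induced (0.209 per Mb) and 30 non-induced (0.330 per Mb). The explanations below were weighed for X only. The lower number of genes on X is not the whole cause, since chromosome 12, with 5.66 genes per Mb as on X, had 1.68 induced peaks per Mb against 0.0820 on X. Avoidance of X by HA-Fbxl10 does not account for the non-induced list if HA-Fbxl10 was absent without doxycycline, which was not tested. That list had 6.43% (4.73 to 8.55) of the X peaks the autosomal rate predicts. For the induced list, with 3.67% (2.01 to 6.15), avoidance stays open. If cells had 1 copy of X and scores were halved, 80.3 induced and 24.96 non-induced X peaks might be left, and 14 and 47 were found (6 and 41 outside the last 2 Mb). The induced count lay below its prediction (interval 7.65 to 23.5) and the non-induced count above it (34.5 to 62.5). Halved scores alone thus match neither list. The relation of score to copy number was assumed, and filtering by the authors was not tested, so a part of 1 copy and filtering stay open.

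Peaks shared by both lists were concentrated: 9 bins of 1 Mb held 86 of 185 (46.5%), among them 3 adjacent bins on chromosome 4 from 145 to 148 Mb with Zfp genes and Rex2, and bins with Speer4 genes on chromosome 5 and Sp100, Sp110 and Sp140 on chromosome 1. The clusters in these bins are not the whole cause, since outside them the overlap was still 3.13 times random (99 peaks, random maximum 50). Bins with fewer than 3 shared peaks stayed in, and the placements did not exclude unmappable sequence. Repeats elsewhere were therefore not tested and stay open. Sites occupied by HA-Fbxl10 without doxycycline could also give the rest. Of the shared peaks outside these bins 38.4% (28.8 to 48.7) were at a border, between random placements and induced-only peaks. Open chromatin that the antibody precipitates without the tag would give the same, so these cannot be told apart.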

How the results depend on the processing

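Of the main values, 24 comparisons with an alternative kept their direction and side of the threshold, or for counts stayed within 1.5 times, and 8 did not. The overlap of the lists ranged from 1.86% to 4.64% and was above random in every setting run, and the border odds ratio from 15.9 to 39.5. With scores at or above the joint median the lists held 3260 induced and 4759 non-induced peaks, 5 induced gene lists and 1 non-induced gene list lay above the other genes, and 1 list passed the direct comparison, all on fewer peaks by construction and with a common score scale assumed. With lists of equal size 1 list passed the direct comparison. With 1 gene per 100 kb, chosen after the data were seen, 3 induced gene lists (developmental factors, signalling and immediate early genes) and 1 non-induced list lay above, on fewer genes by construction. For Hox genes the direct comparison turned from an odds ratio of 0.157 to 1.8 within 5 kb, and the cause was not tested. For single gene lists, 15 values passed in the main setting; of their 69 comparisons with an alternative 47 kept the call, 21 lost it and 1 reversed. Of 176 comparisons of the 42 values that had not passed, 3 gained a call. Not run were the alternatives that need a genome sequence: those on repeats, CpG content and background stratified by promoter CpG. No paired analysis was possible because each condition had 1 list. Unknown depth limits every statement on peaks missing from a list.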

Other observations

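Some gene families besides the olfactory receptors were nearly free of induced peaks. Among 111 families of at least 20 genes with a shared symbol start, a grouping chosen after the data were seen (222 Fisher's exact tests over both lists), 5 passed in the induced list, all below the other genes. Vomeronasal receptor genes (Vmn) had 1 of 355 (0.282%, odds ratio 0.0179, adjusted exact p = 4.17e-19) and cytochrome P450 genes (Cyp) 2 of 99 (2.02%, odds ratio 0.133, adjusted exact p = 0.0116). Keratin-associated protein genes (Krtap) had 0 of 56, which allows up to 5.36% (adjusted exact p = 0.0309), and keratin genes (Krt) 0 of 53, which allows up to 5.66% (adjusted exact p = 0.0378). The Olfr family was the fifth. Neighbouring genes are not independent, so these p-values are too small where genes of a family lie in clusters. The Vmn, Cyp, Krtap and Krt families were not tested with 1 gene per 100 kb. Whether their calls would hold for separate loci is therefore open. RNA polymerase subunit genes (Polr) had 10 of 28 (35.7%, odds ratio 3.60) and mitochondrial ribosomal protein genes (Mrpl) 14 of 49 (28.6%, odds ratio 2.60), which did not pass (adjusted exact p = 0.0759 and 0.0903).

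Induced peaks marked both ends of a gene less often than independent ends would, a comparison made without a test. Of 13960 genes longer than 10 kb, 1995 had an induced peak at 1 border and 30 at both, where independent ends would give 75.6. In the non-induced list 222 genes had a peak at 1 border and 3 at both, where independent ends would give 0.931. Of 2591 induced border peaks 507 (19.6%) reached borders of 2 or more protein-coding genes, as at Ndufaf3, Dalrd3 and Impdh2 or at Col4a1 and Col4a2, and of 332 non-induced border peaks 26 (7.83%) did.

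The highest peaks of each list lay outside protein-coding genes. In the induced list a peak on chromosome 17 (39842653 to 39849083, score 3100) covered the ribosomal RNA pseudogene Rn18s-rs5 and had no counterpart in the non-induced list. Neighbouring peaks on chromosome 10 near 9230019H11Rik scored 3100 and 2570 and had counterparts of 308 and 243. The highest non-induced peak, on chromosome 1 (24611396 to 24616362, score 2479), covered the pseudogenes Gm10222 and Gm10925 and had no induced counterpart. It was followed by peaks on chromosome Y (90794810 to 90803016, score 1579.9) and chromosome 4 (146054963 to 146058087, score 1011), which had induced counterparts of 360.29 and 575.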
